A study of Drosophila melanogaster with 4 samples.

How the data were processed

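The samples were embryos of *Drosophila melanogaster*, Oregon-R strain, wild type, aged 14 to 16 hours, cross-linked in 1.8% formaldehyde per the labels' protocols. The labels list 2 ChIP samples made with an antibody they call H3K36me2 W and 2 input samples. Each ChIP sample has a list of enriched regions, and the authors deposited a further list for the whole series, called the combined list here. It was treated as the authors' value for the ChIP group, with no SD or n. Input files were not analysed here, so no test of ChIP against input was made. Per the labels, input replicate 1 served the list of ChIP replicate 2, and input replicate 2 served the list of ChIP replicate 1. Nothing in the labels says that the replicates came from separate embryo collections, so the spread between them may be technical.

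Reads were aligned with a tool that the submitters' processing notes name as Bowtie 0.12.7. Coordinates are on FlyBase release 5, per the file headers, which also give the length of each sequence. Each region carries a score that the authors deposited, whose scale, log base and normalization to input are not given in the sources used here. The score served to describe, rank and filter regions within a list, to set paired regions of the replicates side by side and, in the closing observations, to compare chromosomes within each list at matched region width by permutation. Width was matched in 4 classes: under 2.5, 2.5 to 5, 5 to 10 and 10 kb or more. A difference of scores has no known unit. The region caller, its threshold and the rule used to combine the replicates are not given in the sources used here. Without read counts the depth of every sample is unknown, and no interval that needs depth is given.

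Start and end positions were read as deposited, 1-based, and the bases covered by each list were counted on the 13 sequences that hold regions, out of 14 named in the headers. Percentages use the full header length of a sequence, which includes bases to which short reads may not map. The large arms are 2L, 2R, 3L, 3R and X, and the heterochromatin scaffolds are the sequences whose names end in Het. A region counted as shared at an overlap of at least 1 base. Shares carry Wilson 95% confidence intervals, which cover counting error only and treat neighbouring regions as independent. Overlap and the Jaccard index, which is the shared bases divided by the bases in either list, were tested by shifting the regions of each sequence by a random offset that wraps round its end (1000 draws, seed 20, one-sided, smallest possible p 0.000999). Ratios of coverage between chromosomes were tested by rotating the coverage of both replicates along the joined sequences (1000 draws, two-sided, smallest possible p 0.002), with Benjamini-Hochberg adjustment over the 3 comparisons, which was added after the raw p-values had been seen. These permutation tests compare positions along the genome. With n = 2, no p-value across replicates was computed. Correlations are across paired regions or across 100 kb bins, which are not independent replicates, so they carry no p-value.

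The overlap test was tried on simulated lists, with regions placed at random on the large arms and chromosome 4 and fewer draws than above. Lists so made lack the clustering of the real regions, so the error rate for clustered regions is unknown. Among 40 pairs of independent lists 5% gave p below 0.05. The chromosome 4 ratio was tried on 20 simulated sets per setting, each a single list made in the same way. With doubled region density on chromosome 4 it came out at 1.81 against 1.84 expected, and with equal density at 1.02 against 1.

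Whether counts in the replicate libraries differ by more than sampling noise could not be tested without reads. The replicate lists differ in region boundaries and scores, with values in the report, and were counted as 2 samples. The named regions follow a rule fixed before the data were examined: in the combined list the 5 highest scores, the 5 widest regions and the 5 longest gaps on the large arms, and in each replicate the 5 widest regions that the other lacks. Other named regions were chosen after their values were seen. Alternatives covered the overlap that counts as shared, the regions scoring above each list's median and those at or below it, merging of regions less than 1 kb apart, a minimum width of 1 kb, the large arms alone, random placement, regions per megabase, bin sizes of 20 and 500 kb, the combined list and each replicate left out. The share of gene bodies covered, the profile along genes and the gene lists planned before the data were examined were not run. They need an annotation of FlyBase release 5, while the gene table used here belongs to release 6, and coordinates were not converted. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.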

Results

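Chromatin carrying H3K36me2, a dimethylated histone H3 lysine associated with transcribed genes, was mapped by ChIP-seq in Oregon-R wild-type *Drosophila* embryos of 14 to 16 hours. The series holds 2 ChIP samples and 2 input samples of a single stage and genotype, so the comparisons it allows are between the ChIP replicates, between the replicates and the authors' combined list, and between parts of the genome. Lists of enriched regions on FlyBase release 5 were available for the ChIP samples. The lists hold no read counts, so sequencing depth is unknown. Scores are the authors' own, on a scale not given in the sources used here.

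Enriched regions covered about the same amount of the genome in each replicate. Replicate 1 had 4133 regions over 28.0 Mb and replicate 2 had 4231 regions over 27.2 Mb. The mean was 27.6 Mb ± 0.563 (SD, n = 2), or 19.8% ± 0.403 (SD, n = 2) of the 139.7 Mb of sequence that holds regions. Median widths were 4919 bp in replicate 1 and 4595 bp in replicate 2, and the widest regions reached 52817 and 48296 bp. Regions over 20 kb numbered 156 in replicate 1 and 137 in replicate 2, and held 14.5% and 12.9% of the covered bases. Wider regions scored higher, with a Spearman correlation across regions of 0.787 in replicate 1 and 0.785 in replicate 2. Neighbouring regions often lay close together, 24.8% of the gaps in replicate 1 and 25.5% in replicate 2 being under 1 kb.

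The replicates marked largely the same places. Of the replicate 1 regions, 3926 of 4133 overlapped a replicate 2 region, which is 94.99% (Wilson 95% interval 94.3 to 95.6). In the other direction the share was 4124 of 4231, or 97.5% (97.0 to 97.9). Shifted lists overlapped in 34.1% and 34.3% of regions on average and never in more than 45.9% and 46.3% (one-sided permutation p = 0.000999 for each direction, the smallest the draws can give). The replicates shared 26.7 of 28.5 Mb, a Jaccard index of 0.934, against a highest value of 0.198 in shifted lists (one-sided permutation p = 0.000999). Both directions and the index measure the same overlap. The tests ask only whether placement was unrelated, so the degree of agreement rests on the shares and the index. The index was 0.939 on the large arms, 0.871 on chromosome 4, 0.860 on the heterochromatin scaffolds and 0.640 on U, the sequence of unplaced scaffolds.

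Regions found in a single replicate were mostly narrow and low in score. The 207 replicate 1 regions without a partner had a median width of 1643 bp and a median score of 0.524, and the 107 such regions of replicate 2 had 1556 bp and 0.562. In the lowest score quintile 78.0% of replicate 1 regions and 89.6% of replicate 2 regions overlapped the other list, while from the third quintile upward the shares were 99.4% to 100%. The widest region of replicate 1 that replicate 2 lacked was 3R 15459416 to 15464172, with a score of 0.549. The next widest were 3R 9906027 to 9909689, U 5767334 to 5770556, X 4967307 to 4970446 and 3L 9693396 to 9696522. The widest of replicate 2 that replicate 1 lacked was 3L 2102854 to 2106453, with a score of 0.750. It was followed by 2LHet 593 to 3345, X 19990041 to 19992676, 3LHet 2432192 to 2434784 and X 19147540 to 19150044. The 2LHet and 3LHet regions scored 1.56 and 1.49, above the replicate 2 median of 1.27.

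**Figure D1:**
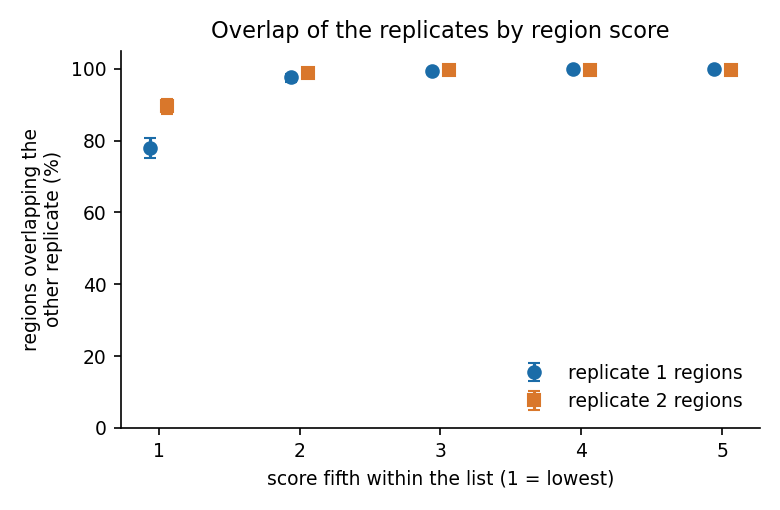
Percent of regions (vertical axis) in each score quintile of a replicate's list (horizontal axis, 1 is lowest) that overlap the other replicate by at least 1 base, with Wilson 95% intervals as bars. The lowest quintile stands at 78.0% in replicate 1 and 89.6% in replicate 2, and all others lie at 97.7% or above.

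Boundaries and scores were close but not identical. A one-to-one overlap joined 3405 regions, 82.4% of replicate 1 and 80.5% of replicate 2. Their boundaries differed by a median of 82 bp, and 29 of 6810 boundaries were identical. No pair had both boundaries or the score in common. Scores of paired regions correlated at a Pearson r of 0.979 and a Spearman rho of 0.978 across regions. The region was wider in replicate 1 in 69.3% of pairs. A further 313 replicate 1 regions met more than 1 replicate 2 region, against 130 in the other direction.

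The combined list held 4311 regions over 29.6 Mb, more than either replicate. Regions of both replicates overlapped 3664 of its regions (85.0%), which had a median score of 1.30. Only replicate 1 overlapped 203 and only replicate 2 overlapped 96. The remaining 348 (8.07%) overlapped neither replicate and were narrow, with a median width of 1297 bp and a median score of 0.397. The combined list took in 99.7% of the bases present in either replicate. Regions of the replicates outside it numbered 2 and 3, and were chosen for mention after their values were seen. Those of replicate 1 were 3L 17893356 to 17894773 and U 8516106 to 8517566. Those of replicate 2 were 2R 16556020 to 16557546, 3R 26678343 to 26679749 and U 2919165 to 2920480, the last with the highest score of that replicate, 3.34.

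Of the 5 highest scores in the combined list, 4 belonged to regions of about 1 kb that neither replicate held. These were 2R 6480626 to 6481626, 3L 23568776 to 23569780 and X 4818792 to 4819796, which share a score of 3.302, and 3LHet 2526072 to 2527072, with 2.98. X 4816836 to 4817836, also of about 1 kb and in neither replicate, shares that score of 2.98 and was left out by the limit of 5. The other was 2L 182918 to 201442, of 18525 bp, with a score of 3.07 in the combined list, 3.05 in replicate 1 and 3.10 in replicate 2.

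The widest combined region was 2R 6365772 to 6418680, of 52.9 kb, which was a single region in replicate 1 and 6 regions in replicate 2. It was followed by 2L 11090958 to 11139856, X 6698668 to 6747380, 2R 9737162 to 9783876 and 2L 12688510 to 12731954. These 5 were covered to between 93.7% and 99.9% in each replicate. The longest stretches of the large arms without a combined region were 2L 16918567 to 17365819, of 447 kb, and 3L 18165899 to 18611573, of 446 kb. Those at 3L 22302059 to 22704937, 2L 14605133 to 15005553 and 2L 15771687 to 16171695 were next. No annotation of this build was used here, so the genes in these places are not named.

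Coverage was uneven along the arms and the unevenness recurred between replicates. Across 1189 bins of 100 kb the Pearson r between replicates was 0.998 and the Spearman rho 0.998. The median bin was covered to 18.7%, 175 bins were empty in both replicates and 112 were covered over more than 50 percent. The fullest bin was X 15600001 to 15700000, at 89.4% in replicate 1 and 89.1% in replicate 2, followed by X 19500001 to 19600000, at 88.9% and 87.4%.

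**Figure D2:**
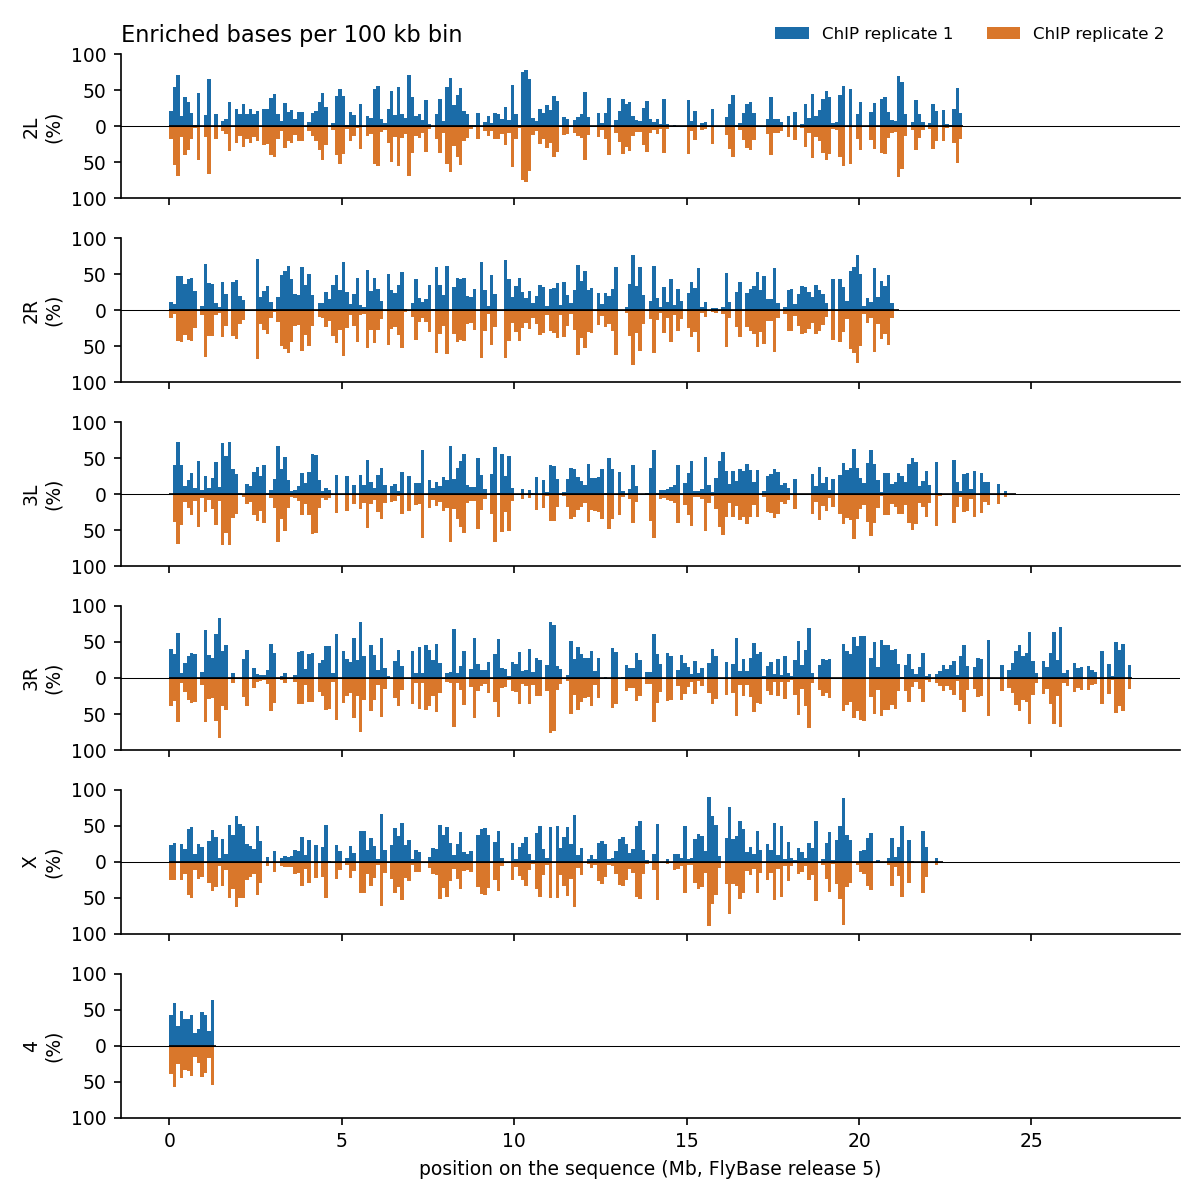
Percent of each 100 kb bin inside enriched regions (vertical axis, replicate 1 upward and replicate 2 downward) by position in Mb on FlyBase release 5 (horizontal axis) for the large arms and chromosome 4. The replicates mirror each other, and the fullest bin lies on X at 89.4% and 89.1%.

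Chromosomes differed in how much of their length was enriched. The large arms were covered to 22.2% ± 0.429 (SD, n = 2), from 20.0% ± 0.405 on 2L to 26.1% ± 0.519 on 2R. Chromosome 4, a small chromosome rich in heterochromatin, was covered to 36.4% ± 2.30 (SD, n = 2), with 38.0% in replicate 1 and 34.8% in replicate 2. The heterochromatin scaffolds were covered to 6.27% ± 0.147 (SD, n = 2), from 3.10% on 3RHet to 13.3% on XHet, and U to 1.22% ± 0.0740.

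Chromosome 4 was covered 1.64 ± 0.0720 times as much as the large arms (SD, n = 2; two-sided permutation p = 0.0220, adjusted p = 0.0330, the adjustment having been added after the raw p-values were seen). Among regions above each list's median score the ratio was 0.737 ± 0.189 (two-sided permutation p = 0.486), and among the others, a comparison added after seeing the data, it was 4.30 ± 0.269 (two-sided permutation p = 0.00400). Because chromosome 4 scored lower, the split itself places most of its regions in the lower-scoring part. The median score was 0.820 ± 0.108 on chromosome 4, 1.31 ± 0.0164 on the large arms and 0.873 ± 0.0212 on the heterochromatin scaffolds (SD, n = 2). The split therefore also places most scaffold regions in the lower-scoring part. The heterochromatin scaffolds were covered 0.283 ± 0.00117 times as much as the large arms (SD, n = 2; two-sided permutation p = 0.0120, adjusted p = 0.0330), over a length that includes bases reads may not map to.

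Coverage of X was not distinguishable from that of the autosomal arms. The ratio of X to the mean of the autosomal arms was 0.976 ± 0.00165 (SD, n = 2; two-sided permutation p = 0.737, adjusted p = 0.737). In regions per megabase it was 1.06 ± 0.0177 (two-sided permutation p = 0.529). Rotated coverage gave ratios between 0.857 and 1.23 in the central 95 percent of draws, so a difference within that range would not have been detected.

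**Figure D3:**
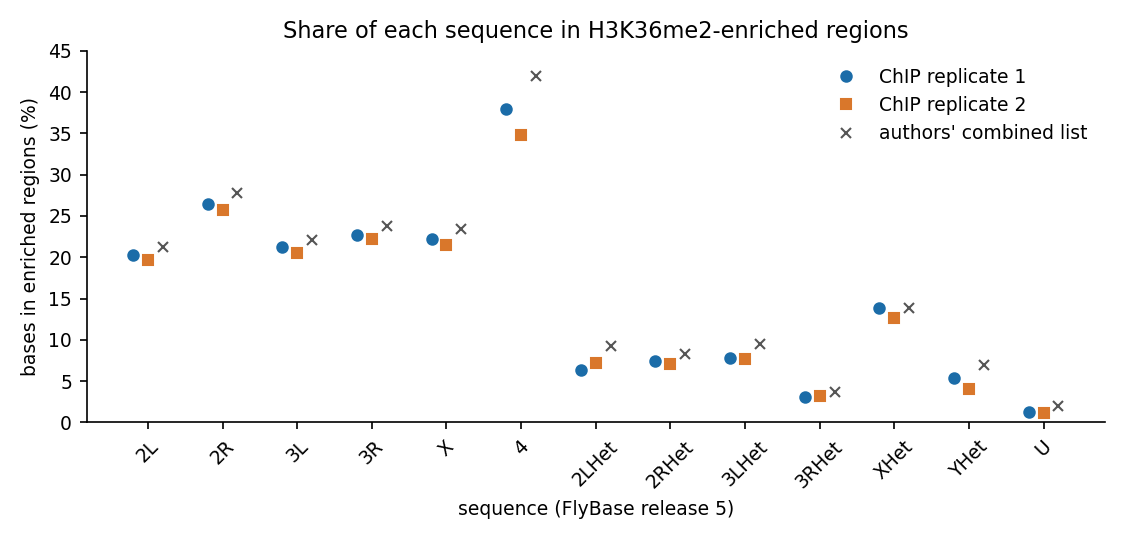
Percent of bases inside enriched regions (vertical axis) for each of the 13 sequences of FlyBase release 5 that hold regions (horizontal axis), with a point for each ChIP replicate and a cross for the authors' combined list. Chromosome 4 stands highest, at 38.0% and 34.8% in the replicates and 41.9% in the combined list, and U lowest of the 13.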

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

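Alternatives were fixed before the data were examined, except the width limit on the combined list, the regions at or below each list's median score and the comparison of each large arm with the others, which were chosen after seeing the data. The overlap of the replicates and their Jaccard index stayed past the threshold under all alternatives run, with shares of 80.7% to 95.7% for replicate 1 and 89.5% to 97.8% for replicate 2 and an index of 0.900 to 0.938. Before adjustment the heterochromatin ratio stayed below 1 and past the threshold, at 0.212 to 0.493. The 0.493 (regions at or below the median score) had two-sided permutation p = 0.0480. The chromosome 4 ratio turned from 1.64 to 0.737 among regions above each list's median score and rose to 4.30 among the others, a split that by construction places most regions of this lower-scoring chromosome in the latter. It was 1.59 to 1.78 under the other alternatives that compare coverage and 2.13 in regions per megabase, all past the threshold before adjustment. The X ratio, not past the threshold in any setting, turned from 0.976 to 1.01 among regions above the median score (0.866 among the rest) and to 1.06 in regions per megabase; the cause was not tested. Keeping only regions above the median score lowered the regions per list to 2090.5, the bases to 20.3 Mb and the large-arm coverage to 16.6% by construction, merging regions less than 1 kb apart lowered the regions to 3133.5, and the combined list gave 29.6 Mb and 23.6%. The share of combined regions found in both replicates was 61.1% when 90 percent of the region had to overlap, 82.4% with reciprocal overlap of 50 percent and 88.9% for regions at least as wide as the narrowest replicate region. Score correlations were 0.905 (Pearson) and 0.904 (Spearman) over all overlapping pairs and 0.975 and 0.975 with reciprocal overlap. Bin correlations were 0.996 (Pearson) and 0.990 (Spearman) for 20 kb bins and 0.998 and 0.998 for 500 kb bins. The minimum width of 1 kb removed no replicate region and so tested nothing. Leaving out a replicate leaves the other's own value, 4133 or 4231 regions, with no spread. Among the large arms, 2R was covered 1.23 times as much as the others (two-sided permutation p = 0.0140), which did not pass adjustment over the 5 arms (adjusted p = 0.0699). No paired analysis was possible because input files were not analysed here. The gene-level alternatives were not run for lack of an annotation of FlyBase release 5. Depth is unknown, and its effect open.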

Other observations

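All tests below were chosen after the result was seen. No biological explanation was tested, since the series holds a single stage and genotype.

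Chromosome 4 combined more coverage than the large arms with lower scores. Narrower regions on chromosome 4 are argued against as the whole cause only as far as 4 width classes can match width. Widths can still differ within a class, and the widest class held 10 and 8 chromosome 4 regions in the replicates. With width so matched, the score difference (chromosome 4 minus large arms, mean of both replicates) was -0.280, against -0.492 unmatched. Its two-sided permutation p was 0.002, the smallest the draws can give (adjusted p = 0.0120 over 6 sequences). The difference was below 0 in all 4 width classes of both replicates, and in the combined list in all but the regions under 2.5 kb, where chromosome 4 had a median of 0.439 and the large arms 0.413. Whether the excess coverage consists of extra weak regions or of regions whose scores are lower throughout stays open, as does a difference in read mapping or input depth, because input reads were not analysed here.

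Of the 348 combined regions found in neither replicate, 176 were narrower than 1301 bp, the width of the narrowest replicate region. The other 172 were at least that wide, which does not exclude a lower minimum width in the combined list as their cause. The same site could be narrower in a replicate, since boundaries of regions paired between the replicates differed by a median of 82 bp. For the narrow ones this cause also stays open. The combined list takes in nearly all replicate bases, and a region that overlaps a replicate is then seldom so narrow. Of all 348, 86.5% lay in the lowest score quartile of the list. This cannot tell signal near a calling threshold from narrow width, since score rose with width in the combined list (Spearman correlation 0.805). All combined regions under 2.5 kb on the large arms had a median score of 0.413. The low median score of the 348 was known when this was tested, and the threshold itself is unknown.

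The 7 regions under 1301 bp in the top score quartile of the combined list lay in neither replicate, and 5 of them shared their score exactly with another region of the list. Such ties made up 19.7% of all combined regions under 1301 bp and 2.97% of the whole list. Ties were not particular to the combined list. They made up 3.92% of replicate 1 regions and 5.96% of replicate 2 regions, where tied regions had median widths of 2203.5 and 2228.5 bp.

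Regions on X scored slightly higher than those on the autosomal arms, with median scores of 1.37 ± 0.00145 and 1.30 ± 0.0165 (SD, n = 2). Different widths on X are argued against: regions on X were narrower in both replicates (median 4904.5 against 5146.5 bp and 4484.5 against 4804 bp), while wider regions scored higher, and matching width raised the difference from 0.0741 to 0.0943. In the combined list regions on X were also narrower (median 4974 against 5110 bp), yet matching lowered the difference from 0.0545 to 0.0461, which goes against that reading. The matched difference itself missed the threshold after adjustment (two-sided permutation p = 0.0180, adjusted p = 0.0539 over 6 sequences). In the combined list its two-sided permutation p was 0.0939. X was higher in 8 of 8 pairs of replicate and width class, but the replicates hold largely the same regions, so these pairs are not independent. Chance and differences in input depth stay open, since input reads were not analysed here.

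As a separate hypothesis, coverage might fall towards the centromere end of each assembled large arm. The most proximal megabase of the 5 large arms was covered to 17.9% on average, against 22.4% in shifted lists (central 95 percent 16.8% to 28.5%, two-sided permutation p = 0.138). A fall within the assembled arms was thus not shown. The heterochromatin scaffolds, which hold pericentromeric sequence, were not part of this test. They were covered to 6.27% against 22.2% on the large arms, over a length that includes bases reads may not map to. The arms differed: 3L had 8.70% and 7.74% and X had 10.8% and 10.5% in the replicates, while 2R and 3R had 25.3% to 27.4%.

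All starts and ends in the combined list are even numbers, against 49.1% to 51.0% in the replicate lists.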
